A study of Mus musculus with 2 samples.

How the data were processed

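Total RNA was sequenced from 2 libraries of mouse cells that the labels call megakaryocytes, the bone marrow cells that shed platelets. The cells were primary cells of adult male C57BL/6J mice aged 5 to 6 weeks, per the labels. The isolation protocol is known here only by its title, which names erythroid cells and megakaryocytes from bone marrow; its text was not used here. Ribosomal RNA was removed and libraries were made with a ScriptSeq kit from 100 ng of RNA, per the labels. The stated size range was 221 to 1000 nucleotides for library 1 and 200 to 1000 for library 2. The labels give the libraries as biological replicates 1 and 2 of 1 group and name the same donor for both. There was no second group, and so no contrast between conditions.

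The authors' deposited tables give one row per gene and one row per transcript for each library. Reads were mapped to mm10 with the GENCODE M4 annotation, per the text file deposited with each library. The aligner, the quantifier and their versions were not given in the sources used here. The column names are those that RSEM writes. The deposited expected counts are estimated read counts per gene or transcript, are not whole numbers and were not normalized. The deposited TPM values are transcript shares on a fixed total over all rows of a table, spike-in sequences and short numbered sequences included. A posterior mean TPM and an interval for TPM of unstated level were also deposited. The deposited FPKM values are fragment counts scaled by length and by the assigned fragments of the library. The deposited percent of a gene's TPM assigned to each transcript was used for transcript shares. Deposited effective lengths are in bases. The ratio and log2 values given here were computed from these columns and none was deposited by the authors.

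Summed expected counts were 42703213 in library 1 and 50532821 in library 2, of which 37377787 and 44809299 lay in nuclear protein-coding genes. At an effective length of 1000 bases, 1 TPM was worth 100.2 counts in library 1 and 114 counts in library 2. A limit of 3 counts was used for genes at 0. Spike-in rows had 0 counts in both libraries, and the 26248 numbered rows held 8.88 and 4 counts. Limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

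Gene symbols, gene types and coordinates came from GENCODE M21, which uses the same genome build, by gene ID without version. Of 43346 mouse gene IDs among 69691 rows, 42462 matched and 884 did not. The match left 21461 nuclear protein-coding genes. One member of the erythroid list and one of the lists added later had no row and were not analysed here.

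Before the data were examined, 20 gene lists, the tests and a rule for named genes were fixed. The lists cover 10 cell types and 10 other groups. Members also found in another fixed list number 18 of the 30 megakaryocyte and platelet markers, 6 of the alpha granule cargo, 6 of the platelet signalling genes, 3 of the dense granule genes, 2 of the eicosanoid genes, and 1 each of the erythroid markers, the megakaryocyte transcription factors and the cytoskeleton genes; the other lists share none. The rule named up to 4 members of each list with the highest mean TPM, 10 for the megakaryocyte markers and transcription factors, and any of these markers or factors under 1 TPM in both libraries. It also named the 10 nuclear protein-coding genes and the 5 other genes with the highest mean TPM. Mitochondrial protein-coding genes were counted in neither group. It further named the 8 genes with the largest log2 ratio in each direction among genes with a mean count of 100 or more that passed the test between libraries. For transcripts it named 10 fixed genes and up to 10 list genes at 10 TPM or more whose leading transcript differed. Some genes that the rule takes are not reported here by name; they remain in the medians and counts of their lists. Another 6 lists were written after the levels of the first lists were known and before their own values were seen.

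For each list, the median over its members of the mean TPM was set against 10000 random lists of the same size drawn from nuclear protein-coding genes at a mean of 0.1 TPM or more. Members under 0.1 TPM stayed in the list. A list with a median of 0.1 TPM or less therefore stands at or near percentile 0 by construction. The percentile of a median among random lists is a description of these libraries and not a test. Values are given as mean ± SD over the 2 libraries.

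Expected counts were rounded to whole numbers for count methods. Scaling factors and a common biological coefficient of variation (BCV) were estimated with edgeR 4.0.16 (TMM, intercept only) in R 4.3.3 over genes with a mean count of 10 or more. Size factors and gene-wise dispersions from DESeq2 1.42.0 were an alternative. Each gene was compared between libraries with a two-sided exact binomial test given the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05. With 1 library on each side this test compares 2 libraries beyond counting error, and its p-values hold no spread between replicates. Log2 ratios are library 2 over library 1, with 1 count added to each. A list's median log2 ratio was set against 10000 random lists matched on mean expression in 20 bins. A list is said to lie outside the random range when its percentile is under 2.5 or over 97.5, a range set after the data were examined. Correlations used log2(TPM + 1) across genes, which are not independent replicates.

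The test was tested on simulated Poisson counts for 12081 genes with 200 changed genes. It called 54 of 66 genes changed 1.5-fold, 61 of 67 changed 2-fold and 65 of 67 changed 4-fold, and 11 of 11881 unchanged genes. These counts held counting error alone, the spread that the test assumes. The few calls among unchanged genes therefore do not show how often it calls genes at the spread between replicates. On simulated counts for the same 12081 genes with a BCV of 0.05, 0.1 or 0.2, edgeR recovered 0.0499, 0.101 and 0.201. A simulated list of 20 genes lowered by 1 on the log2 scale came out at a median of -1.01 (percentile 0), and before lowering at -0.01 (percentile 16.9), again among 12081 genes. The lowering was applied to the log2 ratios and not to the counts. The median therefore moved by 1 by construction, and only the percentile was an outcome.

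Alternatives covered each library alone, other TPM thresholds, FPKM, posterior mean TPM, TPM rescaled to nuclear protein-coding genes, thinning of the deeper library, other backgrounds, pseudocounts, scalings, count filters and an assumed BCV. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.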

Results

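Total RNA from cells labelled megakaryocyte was measured in 2 libraries, numbered 1 and 2 as in the labels, with summed expected counts of 42703213 and 50532821. The libraries form a single group, so the comparisons are between genes and gene groups within the libraries and between the libraries themselves. Values are TPM as mean ± SD over the 2 libraries (n = 2) unless stated otherwise. Coordinates are on mm10.

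The first question was how strongly these libraries express the genes of the cell type they are labelled with. Most megakaryocyte and platelet genes were near 0. The platelet glycoproteins Gp5 and Gp6, the 12-lipoxygenase Alox12 and the inhibitory receptor Mpig6b had 0 counts in both libraries, which for Gp5 allows up to 0.0152 TPM in library 1 and 0.0134 TPM in library 2. Pf4, the platelet chemokine platelet factor 4 (chromosome 5, 90772435 to 90773383), had 0 and 3 counts, Ppbp 0 and 7, and Gp9 0 and 5. Vwf, which encodes von Willebrand factor (chromosome 6, 125546774 to 125686679), had 30 and 24 counts and stood at 0.095 ± 0.0354 TPM.

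Of the 30 megakaryocyte and platelet markers, 21 lay under 1 TPM in both libraries and 9 at 1 TPM or more in both. The median over the list was 0.1 TPM, with library medians of 0.13 and 0.14 TPM. The 3-count limit at the median marker was 0.0164 TPM in library 1 and 0.0121 TPM in library 2. Besides the genes above, the low members included Itga2 (0.72 ± 0.0849), P2ry12 (0.6 ± 0.0283), Selp (0.435 ± 0.163), Pear1 (0.435 ± 0.304), F2rl2 (0.14 in both), Tubb1 (0.105 ± 0.0495), Slc35d3 (0.04 ± 0.0283) and Gp1bb, Rab27b, Treml1, Gp1ba and Mmrn1, which had 0 counts in library 1 and from 1 to 53 counts in library 2. The highest members were Plek at 34.7 ± 2.24 TPM, Cd9 at 18.2 ± 0.29, Tbxas1 at 9.88 ± 1.18, Thbs1 at 9.18 ± 0.247 and Nbeal2 at 8.7 ± 1.71. Both chains of the fibrinogen receptor were detected, Itgb3 at 5.79 ± 0.184 TPM and Itga2b at 4.08 ± 1.15 TPM. The protein-coding transcript Itga2b-201 held 39.8% of the Itga2b TPM in library 1 and 22.1% in library 2. The noncoding Itga2b-207 held 32.2% and 34.2%, so the gene level overstates the coding form. P2rx1 stood at 2.64 ± 0.304 TPM and Clec1b at 1.08 ± 0.0566 TPM. The list median was below that of all 10000 random lists of expressed genes (percentile 0), which a median of 0.1 TPM nearly fixes in advance. Against all annotated protein-coding genes, many of them silent, its percentile was 31.3. Because these marker genes go against the label, the libraries are called the libraries labelled megakaryocyte throughout.

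The next question was which other bone marrow cell types were represented. By list median, neutrophil genes were the highest of the cell type lists in the libraries labelled megakaryocyte. Bulk RNA does not show which cells these transcripts came from. S100a8 and S100a9, the subunits of calprotectin, stood at 7598 ± 469 and 3949 ± 738 TPM, Ngp at 992 ± 163 and Retnlg at 513 ± 9.38. All 19 neutrophil markers were at 10 TPM or more in both libraries, 9 of them at 100 TPM or more, with a list median of 86.2 TPM (percentile 100). Monocyte and macrophage markers had a median of 27.9 TPM (percentile 100), led by the lysozyme gene Lyz2 at 7000.3 ± 1458 TPM, Ly6c2 at 835 ± 93.6, the chemokine receptor gene Ccr2 at 417 ± 47.7 and Ms4a6c at 182 ± 41.2. The complement genes C1qa, C1qb and C1qc, which tissue macrophages express and which were singled out after their values were seen, lay under 1 TPM in both libraries. Reads of Ly6c2 may be shared with its near-identical neighbours, so its level is uncertain. The TPM of S100a8 rests on a short effective length of 172 bases in library 1 and 160 in library 2. Its counts, 125269 and 144885, were fewer than those of Lyz2, at 623485 and 942951.

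Mast cell, basophil and eosinophil markers had a median of 16.8 TPM (percentile 98.1). The basophil proteases Mcpt8 and Prss34 stood at 87.6 ± 8.57 and 69.2 ± 9.9 TPM, the eosinophil granule gene Prg2 at 70.1 ± 6.68 and the IgE receptor gene Ms4a2 at 20.8 ± 1.6. Dendritic cell markers had a median of 10.2 TPM (percentile 87.1), with the antigen presentation genes Cd74 at 43.9 ± 3.2, H2-Ab1 at 41.3 ± 11.3 and H2-Aa at 26.6 ± 4.33, and the lectin gene Cd209a at 22.6 ± 4.75. Erythroid markers had a median of 1.52 TPM (percentile 0.82; 2.16 TPM in library 1 and 1.0 in library 2), with the globin genes Hba-a2 at 47.2 ± 28.1, Hbb-bt at 11.6 ± 1.68 and Hbb-bs at 11.1 ± 3.6, and the transferrin receptor gene Tfrc at 9.58 ± 2.06. Against all annotated protein-coding genes the erythroid percentile was 80.1, so how low these markers stand depends on the background. Globin copies share reads, so the level of each copy is uncertain.

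The remaining cell type lists stood low against random lists of expressed genes. Against all annotated protein-coding genes, T and NK cell markers stood at percentile 77.2 and stem and progenitor markers at 49.1. Endothelial and stromal markers then stood at 34.4 and B cell markers at 31.0. The B cell percentile of 0 among expressed genes was fixed by a median under 0.1 TPM. T and NK cell markers had a median of 1.68 TPM (percentile 2.8), with Gzma at 8.7 ± 4.75, Cd3g at 8.52 ± 1.91, Ncr1 at 3.56 ± 1.77 and Nkg7 at 2.62 ± 0.644. Stem and progenitor markers had a median of 0.26 TPM (percentile 0.01; 0.4 and 0.12 TPM in libraries 1 and 2), and their highest members were Cd48 at 68.3 ± 11.2, Cd34 at 5.52 ± 0.354, Flt3 at 3.95 ± 0.113 and Mllt3 at 3.24 ± 1.82. B cell markers had a median of 0.04 TPM (percentile 0; 0.06 and 0.01 TPM in libraries 1 and 2), although the immunoglobulin gene Ighm reached 86.0 ± 4.02 TPM. Cd79b followed at 3.67 ± 0.785, Blnk at 0.56 ± 0.0566 and Igll1 at 0.17 ± 0.0283. Endothelial and stromal markers had a median of 0.11 TPM (percentile 0), with Cxcl12 at 2.91 ± 0.368, Bglap at 1.46 ± 0.127, Col1a1 at 0.72 ± 0.834 and Col1a2 at 0.355 ± 0.0636.

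**Figure D1:**
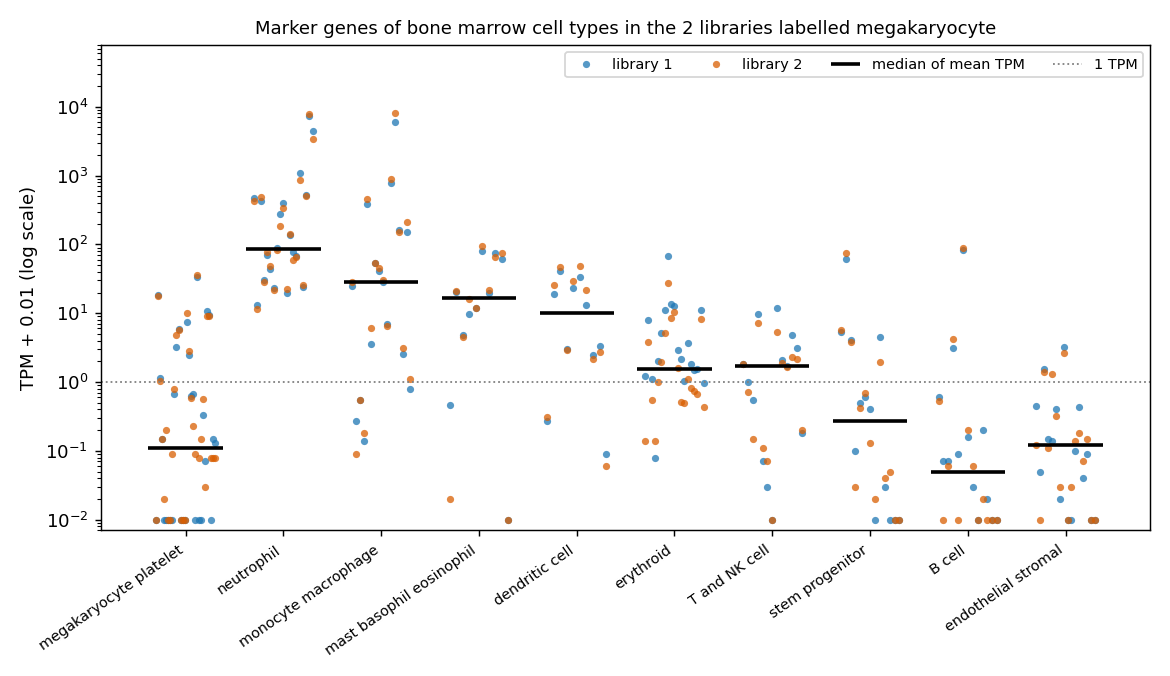
TPM plus 0.01 (log axis) of each marker gene in the 10 cell type lists, with blue points for library 1, orange points for library 2, a black bar at the list median of mean TPM and a dotted line at 1 TPM. The neutrophil median lies at 86.2 TPM and the megakaryocyte and platelet median at 0.1 TPM, and points at the bottom edge are genes at 0 TPM.

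The neutrophil median, which is the level of Itgam, exceeded the megakaryocyte median 683-fold in library 1 and 597-fold in library 2. Such ratios compare list medians and do not measure the share of any cell type. For monocyte and macrophage markers the ratios were 202 and 212, for mast cell, basophil and eosinophil markers 122 and 132, for dendritic cell markers 62.7 and 87.7, for T and NK cell markers 13.2 and 11.7, and for erythroid markers 16.6 and 7.14. Endothelial and stromal medians lay at 0.654 and 0.75 of the megakaryocyte median, B cell medians at 0.462 and 0.0714, and stem cell medians at 3.08 and 0.857. A second measure took the mean of log2(TPM + 1) over each list in place of the median. The added 1 draws lists of low TPM together by construction. By this measure the distances were smaller, except for endothelial and stromal markers. For these the mean megakaryocyte over list ratio went from 1.43 to 1.6. The megakaryocyte over list ratio was then 0.0135 for neutrophil, 0.075 for monocyte and macrophage, 0.148 for mast cell, basophil and eosinophil, 0.247 for dendritic cell, 0.564 for erythroid and 0.849 for T and NK cell markers, the last close to equal. With markers under 1 TPM left out of each list, the megakaryocyte median was 0.096 of the neutrophil, 0.19 of the monocyte, 0.397 of the mast cell, basophil and eosinophil and 0.421 of the dendritic cell median, and 5.7 times the endothelial and stromal median. The direction then turned for the erythroid markers, where the megakaryocyte median was 5.33 times as high. It also turned for the T and NK cell markers, at 3.29 times as high, and for the B cell markers, at 0.184 of theirs. For the stem cell markers, whose direction already differed between the libraries, the megakaryocyte median was 1.7 times as high. This filter acts on the measured levels and so raises a list median by construction. It removed 21 of 30 megakaryocyte, 2 of 19 erythroid, 6 of 13 T and NK cell and 9 of 13 stem cell markers. Of the B cell markers it removed 11 of 13, and of the endothelial and stromal markers 13 of 16. No direction is drawn from these ratios.

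Among genes grouped by megakaryocyte function, alpha granule cargo stood low and cytoskeleton genes high against random lists of expressed genes. Transcription factor, dense granule, platelet signalling and eicosanoid genes lay inside the range of those lists. These readings depend on the background. Against all annotated protein-coding genes, many of them silent, alpha granule cargo stood at percentile 46.9 and cytoskeleton genes at 100. Transcription factor and platelet signalling genes then stood at 99.9, dense granule genes at 99.7 and eicosanoid genes at 97.3. Megakaryocyte transcription factors had a median of 8.96 TPM (percentile 90.2), and 18 of 20 were at 1 TPM or more in both libraries. Nfe2 stood at 60.9 ± 1.35 TPM, Cbfb at 54.3 ± 3.23, Fli1 at 26.3 ± 0.0566, Lmo2 at 25.1 ± 0.311, Mafg at 16.5 ± 0.559, Lyl1 at 16.0 ± 1.44, Ldb1 at 16.0 ± 1.32, Runx1 at 13.6 ± 2.08, Myb at 11.0 ± 0.969 and Etv6 at 9.75 ± 1.06. Several of these factors, Runx1 and Fli1 among them, are also used in other blood lineages. Gata1, the erythroid and megakaryocyte factor on chromosome X, was at 1.72 ± 0.247 TPM, and Tal1 at 0.57 ± 0.113 was the only factor under 1 TPM in both libraries.

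Alpha granule cargo had a median of 0.278 TPM (percentile 0; 0.215 and 0.4 TPM in libraries 1 and 2), with 14 of 22 members under 1 TPM in both libraries. Its highest members were F13a1, the A chain of coagulation factor XIII, at 419.6 ± 46.4 TPM, Apoe at 163 ± 17.7, Srgn at 129.6 ± 7.74 and Tgfb1 at 10.5 ± 0.488. F13a1, Apoe and Srgn are also expressed by monocytes and macrophages. Dense granule and granule biogenesis genes had a median of 6.95 TPM (percentile 73.8), with Rab27a at 40.4 ± 3.01, Lyst at 34.1 ± 1.53, Rab32 at 28.6 ± 2.6 and Ap3b1 at 24.5 ± 1.97. Platelet signalling genes had a median of 6.05 TPM (percentile 65.1). Fcer1g stood at 268 ± 7.07, Gnai2 at 226 ± 18.3, Lyn at 88.6 ± 8.75 and Vav1 at 81.7 ± 8.44.

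Cytoskeleton and proplatelet genes had a median of 40.5 TPM (percentile 100), with Actb at 1911 ± 39.5, Flna at 545 ± 20.1, Cfl1 at 493 ± 39.0 and Cdc42 at 284 ± 21.6. Tubb1, the platelet beta tubulin, was among its 3 members under 1 TPM in both libraries. Eicosanoid synthesis genes had a median of 8.28 TPM (percentile 74.3), led by Alox5ap at 255 ± 27.4, the leukotriene pathway activator, with Pla2g4a at 20.2 ± 4.75, Alox5 at 15.4 ± 0.325 and Tbxas1 as above. Cell cycle genes had a median of 20.6 TPM (percentile 100), and 30 of 32 were at 1 TPM or more in both libraries. Top2a stood at 182 ± 11.1, Rhoa at 158 ± 3.54, the proliferation marker Mki67 at 129.9 ± 7.86 and Ccna2 at 66.3 ± 6.82. Interferon response genes had a median of 7.57 TPM (percentile 79.2), with Ifitm3 at 202 ± 8.53, Mx1 at 28.4 ± 0.262 and Bst2 at 21.2 ± 0.0283. Immediate early and stress genes had a median of 10.4 TPM (percentile 95.8), with Fos at 107 ± 0.134, Klf6 at 49.1 ± 3.73, Btg2 at 47.5 ± 0.834 and Zfp36 at 45.4 ± 3.06. The sex label was checked with 5 genes, of median 5.23 TPM (percentile 50.1). Xist had 0 counts in both libraries, which allows up to 0.005 and 0.0044 TPM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 34.6 ± 1.97, 13.2 ± 0.375, 5.23 ± 0.962 and 4.34 ± 0.12 TPM.

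Across RNA classes, small noncoding RNA took most of the TPM. Its share was 70.8% ± 2.01 of summed TPM and 6.88% ± 0.522 of summed expected counts, against 25.4% ± 1.98 and 88.1% ± 0.809 for nuclear protein-coding genes. The 5 highest genes outside the protein-coding class were Rn7sk, the 7SK RNA, at 130829.7 ± 16671 TPM, the small nucleolar RNA gene Gm22422 at 117784 ± 3993, the signal recognition particle RNAs Rn7s2 and Rn7s1 at 51750.3 ± 1917 and 51681 ± 2006, and the small nuclear RNA gene Gm24950 at 37480.1 ± 7071. Rn7s1 and Rn7s2 are near-identical copies that share reads. Gm22422 had 25537 and 19929 counts over an effective length of 2.22 and 1.45 bases, so its TPM rests on a length close to 0. TPM of protein-coding genes is scaled down by these short RNAs in both libraries. Long noncoding RNA held 0.723% ± 0.0594 of TPM and mitochondrial protein-coding genes 0.902% ± 0.09.

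Among nuclear protein-coding genes, S100a8 on chromosome 3 (90668978 to 90670035), Lyz2 on chromosome 10 (117277331 to 117282321) and S100a9 on chromosome 3 (90692632 to 90695721) were the highest. They were followed by Hist2h2aa1 at 3562 ± 662 TPM, the elongation factor gene Eef1a1 at 2542 ± 139, Actb, Hist1h4d at 1875 ± 471, Tmsb4x at 1623 ± 192, Rpl36a at 1176 ± 237 and Hist2h2ac at 1152 ± 264. The 10 highest genes took 12.6% of nuclear protein-coding TPM in library 1 and 12.9% in library 2. Histone gene copies share reads and their single levels are uncertain. At 1 TPM or more, 9383 of 21461 nuclear protein-coding genes were detected in library 1, 9351 in library 2 and 9100 in both. A threshold of 5 TPM left 5703 in both.

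Gene levels in both libraries were close. Pearson's correlation of log2(TPM + 1) across 21461 genes was 0.993 and Spearman's was 0.975. The edgeR common BCV between the libraries was 0.241 over 12081 genes with a mean count of 10 or more. It was 0.154 at a mean count of 100 or more, and the median gene-wise value from DESeq2 was 0.0873.

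**Figure D2:**
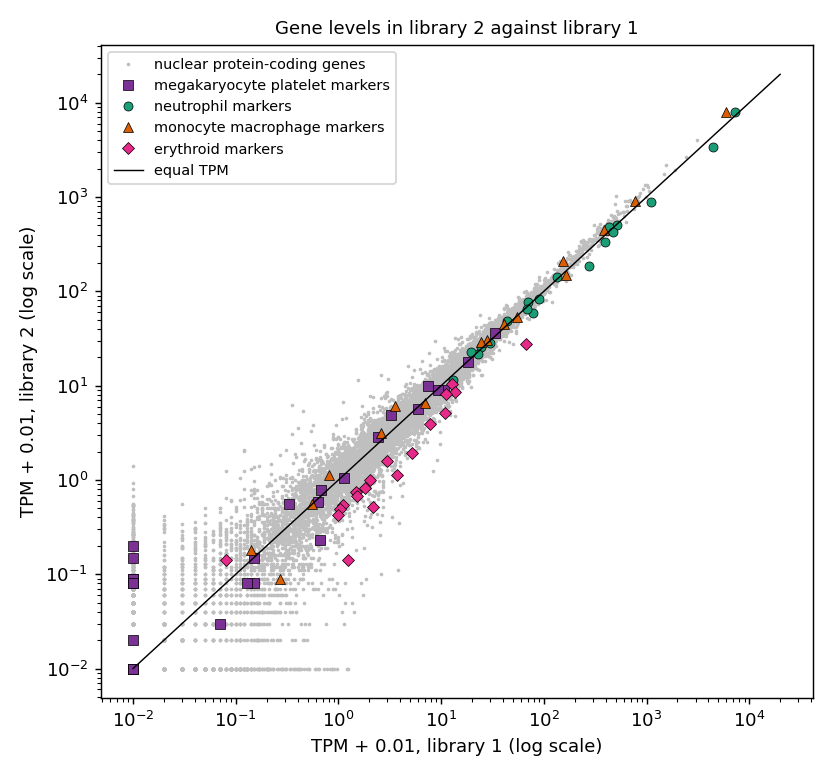
TPM plus 0.01 in library 2 against library 1 (both axes log) for nuclear protein-coding genes in grey, with megakaryocyte and platelet markers as purple squares, neutrophil markers as green circles, monocyte and macrophage markers as orange triangles and erythroid markers as pink diamonds; the line marks equal TPM. Pearson's correlation of log2(TPM + 1) was 0.993, and most erythroid markers lie under the line.

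A comparison of the libraries with each other asked which genes differed beyond counting error. Cxcl2, a chemokine that attracts neutrophils (chromosome 5, 90903871 to 90905938), was higher in library 2, with 127 counts in library 1 and 1063 in library 2 (log2 ratio 2.81, adjusted p = 3.4e-149, exact binomial test with Benjamini-Hochberg adjustment). In the opposite direction, Klf1, the erythroid transcription factor (chromosome 8, 84901928 to 84905291), had 283 and 75 counts (log2 ratio -2.15, adjusted p = 2.5e-36, same exact test). Klra8, an NK cell receptor gene, had 202 and 33 counts (log2 ratio -2.82, adjusted p = 6e-36, same exact test). Il1r1, which encodes the interleukin 1 receptor, had 168 and 42 counts and Inhba, a subunit of activin A, 249 and 70 counts. The other genes among the 8 highest in library 2 were Gm2026, N4bp3, Gm14410, Lsm7, Usp50, Qtrt1 and Gm12166, with log2 ratios from 2.03 to 4.04. Gm2026 and Gm14410 were not checked for near-identical copies and may share reads with them, so their ratios are uncertain. Cadm3, Zfp395, Tom1l1 and Paqr9 completed the 8 highest in library 1, whose log2 ratios ran from -2.06 to -2.82.

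In total 7894 of 12081 genes differed, 3980 higher in library 2 and 3914 higher in library 1. At least a 2-fold ratio was reached by 1141 of them, 516 higher in library 2 and 625 higher in library 1. The test holds counting error alone, and edgeR's exact test at an assumed BCV of 0.1 called 1556 genes. The assumed BCV lay under the edgeR common BCV of 0.241 and above the DESeq2 median of 0.0873. Neither number of genes therefore shows how many exceed the spread between replicates. Replicates of one group have no order, so a direction here describes 2 libraries and no condition.

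Gene groups differed unequally between the libraries labelled megakaryocyte; the members given as examples were chosen after their values were seen. Erythroid markers were lower in library 2, with a median log2 ratio of -1.09 and a percentile of 0 among matched random lists. Of 19 measured, 18 passed the test as lower in library 2, and 18 when adjusted over the list alone. The anion exchanger gene Slc4a1 had 769 and 382 counts (log2 ratio -1.25) and the heme synthesis gene Alas2 had 93 and 26 counts (-2.05). Epor, the erythropoietin receptor, had 11 and 24 counts and did not pass. T and NK cell markers had a median of -0.54 (percentile 1.55), with 8 of 12 lower and 1 higher, and the same numbers adjusted over the list alone. Gzma had 791 and 391 counts (-1.26) and Ncr1 598 and 323 counts (-1.13).

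Neutrophil markers had a median log2 ratio of -0.14 (percentile 0.02), with 13 of 19 lower and 2 higher in library 2, and 13 and 3 adjusted over the list alone. Lcn2 had 18984 and 14566 counts (-0.63) and S100a9 129959 and 108597 counts (-0.51). Monocyte and macrophage markers had a median of 0.15 (percentile 98), with 10 of 16 higher and 4 lower, and the same numbers adjusted over the list alone. Cd14 had 482 and 928 counts (0.70) and Lyz2 623485 and 942951 counts (0.35). Megakaryocyte transcription factors had a median of -0.18 (percentile 0.43), with 13 of 20 lower and 3 higher, and the same numbers adjusted over the list alone. The lowest were Klf1, Gfi1b at -1.09 and Gata1 at -0.97, which erythroid cells also express. Alpha granule cargo had a median of 0.24 (percentile 99.3), with 10 of 18 higher and 3 lower, and the same numbers adjusted over the list alone. At a mean count of 100 or more its median was 0.07 (percentile 76.4), inside the random range.

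Megakaryocyte and platelet markers had a median log2 ratio of -0.01 over the 18 with enough counts (percentile 51.5), 5 higher and 4 lower, and the same numbers adjusted over the list alone. Its members went both ways: Gp1bb had 0 and 35 counts and Rab27b 0 and 53 counts, while Pear1 had 96 and 56 counts and Nbeal2 4639 and 3948 counts, and all 4 passed the test. By TPM, Nbeal2 went the other way, at 7.49 in library 1 and 9.91 in library 2, so its direction is uncertain. Pf4, Ppbp, Gp9, Treml1 and Gp1ba, with 0 counts in library 1 and from 3 to 8 in library 2, had too few counts to be tested. The other 13 lists also lay inside the random range. Among cell types, mast cell, basophil and eosinophil markers had a median of -0.04 (percentile 31.3; 3 of 9 lower and 3 higher) and dendritic cell markers 0.07 (percentile 74; 4 of 10 lower and 5 higher). B cell markers had -0.50 (percentile 17; 3 of 5 lower and 1 higher), stem and progenitor markers -0.34 (percentile 4.2; 4 of 8 lower and 1 higher) and endothelial and stromal markers -0.32 (percentile 25; 2 of 10 lower and 2 higher). Immediate early genes had -0.10 (percentile 3.31; 11 of 20 lower and 6 higher), cytoskeleton genes -0.05 (percentile 4.31; 10 of 21 lower and 7 higher) and platelet signalling genes -0.04 (percentile 12.8; 10 of 30 lower and 10 higher). Dense granule genes had 0.02 (percentile 63.2; 7 of 21 lower and 8 higher), interferon response genes 0.03 (percentile 60; 6 of 18 lower and 8 higher) and cell cycle genes 0.05 (percentile 80.1; 10 of 32 lower and 15 higher). Eicosanoid synthesis genes had 0.07 (percentile 74.8; 1 of 6 lower and 3 higher) and the sex-linked genes 0.01 (percentile 50.5; 1 of 4 lower and 1 higher). Adjusted over the list alone the numbers were the same in these 13 lists, except for 1 higher endothelial and stromal marker and 2 lower eicosanoid genes.

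**Figure D3:**
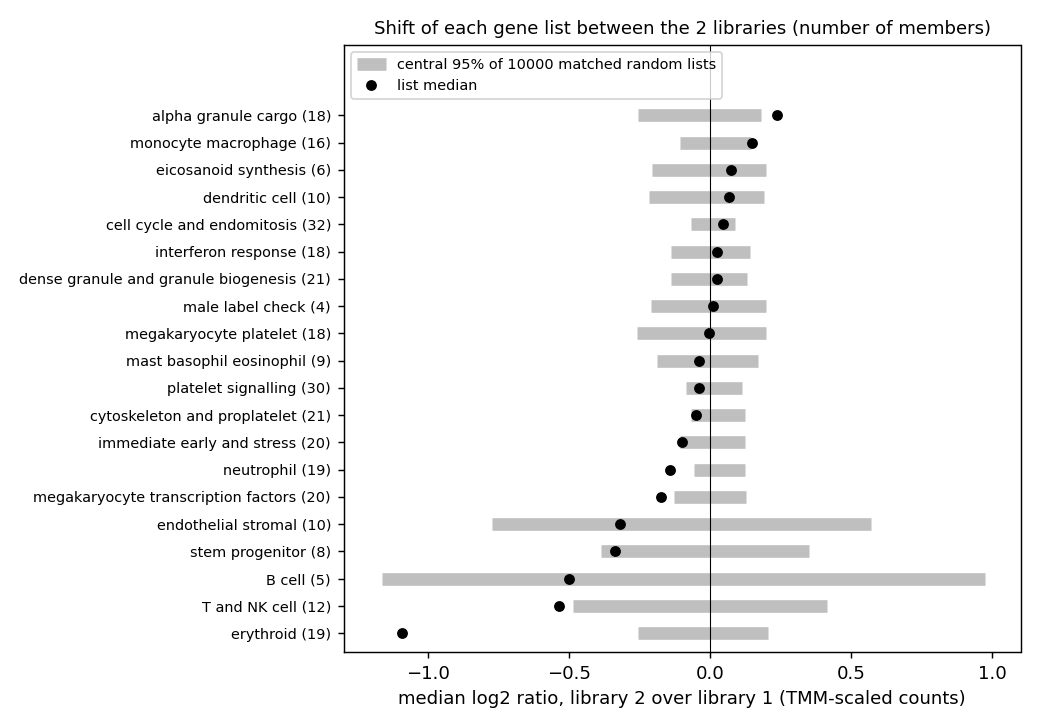
Median log2 ratio of TMM-scaled counts, library 2 over library 1, for each of the 20 fixed lists (points), with the number of members in brackets and grey bars for the central 95% of 10000 random lists matched on mean expression. The erythroid median lies at -1.09, and the megakaryocyte and platelet median at -0.01.

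Transcript estimates were compared to learn whether both libraries gave the same leading transcript. Fli1 was assigned to Fli1-201 for 99.7% ± 0.276 of its TPM and Tpm4, a tropomyosin, to Tpm4-201 for 99.7% ± 0.127. Actn1-201 took 96.4% ± 5.15 of the alpha actinin gene Actn1, Gata1-201 80.3% ± 27.8 of Gata1 and Runx1-201 41.1% ± 3.34 of Runx1. Tpm1 was led by Tpm1-211 in library 1 and by Tpm1-212 in library 2. Itga2b was led by Itga2b-201 in library 1 and by the noncoding Itga2b-207 in library 2, Zfpm1 by the noncoding Zfpm1-202 and Zfpm1-204, and Vwf, with 30 and 24 counts, by Vwf-211 and Vwf-206.

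Of 2794 nuclear protein-coding genes at 10 TPM or more with at least 2 transcripts, 2482 (88.8%) had the same leading transcript in both libraries. The leading transcript held a median of 73.8% of the gene's TPM where it was the same and 44.5% where it differed. Among 97 list genes at this level, 10 differed, namely Itgam, Rasgrp2, Stat3, Mx1, Prtn3, Pla2g4a, Plk4, Irf7, Ldb1 and Myb. In Stat3, Irf7, Prtn3 and Myb the leading transcript of library 1 was a retained intron form and that of library 2 a protein-coding form. Ldb1 showed the opposite order.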

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

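Markers of effective length of 1000 bases or more and markers found in no other list were added after the data were examined; the other alternatives were planned. The median of the megakaryocyte and platelet markers stayed under 1 TPM in every alternative run. It was 0.13 to 0.14 TPM with either library alone, 0.138 with posterior mean TPM, 0.401 with TPM rescaled over nuclear protein-coding genes, 0.287 for markers of 1000 bases or more, 0.0675 for markers found in no other list, and 0.23 as FPKM. Rescaling and FPKM raise the values by their construction. Its percentile rose from 0 to 31.3 against all annotated protein-coding genes, since that background holds silent genes. Other lists rose likewise, dendritic cell markers from 87.1 to 99.2, erythroid markers from 0.82 to 80.1 and the second erythroid list from 0.34 to 71.0. The monocyte and macrophage percentile was 99.99 to 100.0 with either library alone. From means of log2(TPM + 1), the ratios of megakaryocyte to neutrophil, monocyte and erythroid markers were 0.0135, 0.075 and 0.564. The added 1 draws lists of low TPM together by construction. With markers under 1 TPM left out, the ratios were 0.096, 0.19 and 5.33. The low markers left out also turned the ratio to T and NK cell markers from 0.0805 to 3.29, to B cell markers from 8.08 to 0.184 and to stem cell markers from 0.746 to 1.7. Leaving them out removes 21 of the 30 megakaryocyte genes but 2 of the 19 erythroid genes. It raises a list median by construction, so no direction is drawn from these ratios. Detected genes numbered 5703 at 5 TPM. Pearson's correlation was 0.991 with a pseudocount of 0.1 and 0.984 for genes at 1 TPM or more in both, where Spearman's was 0.975. The BCV was 0.277 without a filter, 0.154 at a mean count of 100 or more and 0.0873 from DESeq2 dispersions, and the cause of these differences was not tested. Genes differing numbered 1556 at an assumed BCV of 0.1, which adds spread to the test. Those with at least a 2-fold ratio numbered 1764 without a filter and 1945 over all annotated genes, where more genes were tested. The alpha granule shift was 0.0667 at a mean count of 100 or more. The share of genes with the same leading transcript was 86.7% at 5 TPM and 94.3% at 50 TPM; the cause was not tested. With 1 library alone no such share exists. By counts, protein-coding genes held 88.1% and small noncoding RNA 6.88%, since counts are not divided by length. Among the other values, 141 stayed within their spread or on their side of the random range and 77 moved, 70 to a higher and 7 to a lower value. These numbers do not measure robustness, since many were fixed by construction. List medians as FPKM or rescaled TPM must rise, and a background with silent genes raises percentiles. For ratios and the leading transcript share, a value from 1 library alone always lies within the SD of the 2 libraries. The dendritic cell shift was 0.21 (percentile 98.7), outside the range, at a mean count of 100 or more. No paired analysis was possible because there was 1 group. The quasi-likelihood test of edgeR could not be fitted with 1 library on each side. Depth limits a gene at 0 counts to 3, which is 0.0164 TPM at the median marker in library 1.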

Other observations

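The limits from depth, transcript length and small RNA, and the tests of low counts and of cell shares, were chosen after the result was seen; the lists tested below were written after the first lists were known and before their own values were seen. Of 4 further lists of myeloid genes, the pattern recognition receptors lay inside the range of random lists in the libraries labelled megakaryocyte and the others above it. Myeloid transcription factors had a median of 27.0 TPM (percentile 99.8), with Irf8 at 74.5 ± 4.06, Spi1 at 72.0 ± 12.6 and Zeb2 at 69.7 ± 2.47 TPM. The phagocyte NADPH oxidase, which makes superoxide, had a median of 85.4 TPM (percentile 100.0), led by Cybb at 287 ± 9.78 TPM. Chemoattractant receptors had a median of 22.4 TPM (percentile 98.5), with Cxcr4 at 82.0 ± 3.15 and Ccr1 at 24.8 ± 1.69. Pattern recognition receptors had a median of 9.08 TPM (percentile 79.1), with Tlr2 at 13.9 ± 2.5. Between libraries the median log2 ratios were 0.08 (percentile 83.3), -0.01 (percentile 30.7), -0.07 (percentile 19.7) and -0.04 (percentile 29.7) in the same order, all inside the random range. A second megakaryocyte list had a median log2 ratio of 0.69 over 8 genes (percentile 97.7), with 3 higher and 2 lower, but no direction is drawn from it. Its median was 0.48 (percentile 95.2), inside the random range, with a prior count of 5. Over the 4 genes with a mean count of 100 or more it was -0.08 (percentile 38.6), with 0 higher and 2 lower. The other 4 genes had from 0 to 14 counts in library 1 and from 16 to 52 in library 2.

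Histone and ribosomal protein genes, chosen after their values were seen, were on balance slightly higher in library 2. The cell cycle list stayed inside the random range at 0.05 (percentile 80.1), with 15 of 32 members higher and 10 lower in library 2. Of 62 replication-dependent histone genes, 39 were higher and 8 lower, with a median log2 ratio of 0.11 under TMM, 0.11 under DESeq2 size factors and 0.09 under total counts. Of 81 cytoplasmic ribosomal protein genes, 60 were higher and 7 lower, with medians of 0.16, 0.16 and 0.15. Histone copies share reads, so single copies are uncertain. The small nuclear RNA copy Gm23444 had 15333 counts in library 1 and 15 in library 2, while 14 genes of the length of U2 RNA summed to 329940 and 168820 counts.

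The first pattern is the near absence of megakaryocyte and platelet transcripts. The tables argue against depth, short transcripts and small RNA as the cause: 3 counts were worth 0.0164 TPM at the median marker, 17 of 26 markers of 1000 bases or more lay under 1 TPM, and rescaling over protein-coding genes left a median of 0.401 TPM. A second list of 12 megakaryocyte genes had a median of 0.0625 TPM, at percentile 27.9 against all annotated genes. Its percentile of 0 among expressed genes was fixed in advance, since those random lists held only genes at 0.1 TPM or more. A mislabelled sample predicts such a low median, although an isolation that yielded other cells predicts the same and was not separated from it. Myeloid transcription factors at a percentile of 99.8, beside S100a8 at 7598 ± 469 and Lyz2 at 7000.3 ± 1458 TPM, are consistent with RNA from monocyte or neutrophil lineage cells. Both stay open as hypotheses, since bulk RNA does not separate 1 cell type from a mixture, and no biological explanation was tested because the design has 1 group.

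The second pattern is the lower level of erythroid markers in library 2. Low counts are argued against, since the 17 markers with a mean count of 100 or more had a median log2 ratio of -1.09 (percentile 0). A larger share of all minor cell types in library 1 would lower their markers alike in library 2; T and NK (-0.54), B (-0.50), stem (-0.34) and endothelial and stromal (-0.32) markers go that way, the last 3 inside the random range. Mast cell, basophil and eosinophil markers at -0.039 and dendritic cell markers at 0.07 did not go that way as lists. Their median absolute deviations between members were 0.25 and 0.35, and members went both ways, with 5 of 9 and 4 of 10 lower. Their median levels of 16.8 and 10.2 TPM do not give the share of cells. Whether these 2 lists mark minor cell types is not known. They therefore do not decide whether such a larger share is the whole cause. A second erythroid list of 16 genes stood at a median of 1.17 TPM (percentile 0.34). Its median log2 ratio was -0.75 (percentile 0), with 15 lower by the exact binomial test and 16 adjusted over the list alone. Over its 12 genes with a mean count of 100 or more, the shift was smaller, at -0.51 (percentile 0.06), with 12 lower. Different amounts of RNA from erythroid cells predict such a shift and stay a hypothesis, since no biological explanation was tested.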
